A study of Secale cereale x Triticum turgidum subsp. durum with 48 samples.

How the data were processed

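Total RNA of 48 samples of triticale, a cereal that combines wheat and rye genomes, was hybridised to the Affymetrix Wheat Genome array, with 1 array per sample. Per the labels, root and coleoptile came from the cultivar AC Alta, 7 days after sowing, and all other tissues from AC Certa. Growth stages follow the Zadoks scale, a decimal code for cereal development in which a higher number is a later stage. Per the labels' protocols, RNA of leaf, stem, crease and epiderm was extracted with a silica column kit, and stem RNA passed through a further column to remove carbohydrates. RNA of embryo, endosperm and pericarp was extracted in a guanidine hydrochloride buffer, and RNA of root and coleoptile by centrifugation through caesium chloride, so extraction differs between tissues. All samples were labelled by a protocol with 2 rounds of amplification. Probes designed on wheat sequences meet transcripts of rye origin as well, so a level also depends on how well a transcript matches its probes, and levels of different probe sets were not set against each other, except as the 3' minus 5' difference of a control transcript, which was compared between arrays.

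The deposited values are log2 signals per probe set, made with RMA per the submitters' processing notes. The software version, and which arrays were normalized together, are not given in the sources used here. The values ran from 1.92 to 15, and the array medians from 4.87 to 5.03. Scanner files were not used here. The precision is limited by the number of arrays, 2 to 5 per group. The labels call the replicates biological but do not say that they came from separate plants, so the p-values measure the spread between these samples.

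The array holds 61290 probe sets, and 111 control probe sets were left out, which left 61179 to test. One linear model with a mean for each of the 16 groups was fitted to the 48 arrays with limma 3.58.1 in R 4.3.3, with 32 residual degrees of freedom and moderated variances. All groups shared 1 estimate of the spread per probe set. Tests were two-sided, and p-values were adjusted over the tested probe sets by the Benjamini-Hochberg method. A probe set passed with an adjusted p under 0.05 and a difference of at least 1 log2 unit, a 2-fold difference. Changes across all stages of stem or leaf were tested with limma's moderated F-test, with a range of the group means of at least 1 log2 unit. Each of the 5 seed tissues was compared with the unweighted mean of the other 4. The seed comparison set the mean of the 5 seed tissues against the mean of 4 vegetative tissues, with the stages of stem and leaf averaged first. An interaction contrast tested whether the change from booting to Zadoks 75 differed between flag leaf and stem. A probe set counted as enriched in 1 of 9 tissues when its mean lay at least 2 log2 units above every other tissue, each at an adjusted p under 0.05.

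The platform annotation gave 1 gene for 1273 probe sets (771 genes), several genes for 0, and no gene for 59906. Most of those genes carry a LOC number only, and 13 genes on 19 probe sets have a symbol. Genes were named by a rule. In each comparison it takes, among genes with a symbol that passed and whose groups did not overlap, the 8 with the largest positive and the 8 with the largest negative difference. It adds up to 3 passing members of each fixed gene list, and for enriched tissues the 5 probe sets with the largest margin. No detection calls were used here. Where the lower of 2 means lay under the lowest array median, 4.87, its signal can be background, so the fold is a lower bound and is given as at least that value. No fold is given where both means lay under it. Up to 2 probe sets that rose and 2 that fell per comparison are also given by their identifier; these, and any level of a gene that did not pass, were chosen after their values were seen. Where a gene had more than 1 probe set, the one with the largest difference was used. The further probe sets of petC, CAT1, FBP and TUBA were dim, with no group mean above 6.55, while those of SAHH and THI1.1 had the same sign wherever the named one passed, though not always past the threshold.

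Of 18 fixed gene lists, 15 had no member with a symbol. The cell wall list held XTH, the cell division list TUBA, and the defence list THI1.1 and THI1.2. Set tests had been planned for lists of at least 5 genes and were not run. Over 17 comparisons, XTH passed in 8 over all probe sets and in 8 adjusted over the list alone. TUBA passed in 4 and in 4 adjusted over the list alone. The defence genes passed in 9 tests and in 9 adjusted over the list alone. Because the lists were too small, 2 groups of probe sets were defined from leaf Z13 and root after the data were seen. The leaf-over-root set holds 1792 probe sets at least 3 log2 units higher in leaf Z13 than in root, and the root-over-leaf set holds 1493 at least 3 log2 units lower. They were tested with camera, limma's competitive set test, in the comparisons that use neither leaf Z13 nor root, with a preset correlation of 0.01 and with an estimated correlation. The p-values were adjusted over both sets and those comparisons.

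The procedure was tested on simulated data for 61179 probe sets. The simulated noise was normal and independent between probe sets, with 1 spread per probe set for all groups. In the real data the median SD between replicates ran from 0.13 in stem Z45 to 0.26 in leaf Z23. The recovered shares and false calls therefore hold for equal spread only and do not cover groups with a wider spread. For root against coleoptile, 92.5% of probe sets changed by 1.5 log2 units were recovered, 98.5% of those changed by 2 and 100% of those changed by 3, with 2 false calls. For leaf Z85 against leaf Z75, the shares were 94.0%, 98.5% and 100%, with 3 false calls. The enrichment rule recovered 99% of simulated probe sets with a margin of 3 log2 units, with 0 false calls, and the F-test across stem stages recovered 98% at a range of 2 log2 units, with 4 false calls.

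Groups, comparisons, thresholds, the gene lists, the naming rule and the first set of alternatives were chosen before the data were examined. The alternatives were only the compared arrays in the fit, a filter on dim probe sets, a trended and robust variance, quantile normalization again, median scaling, array weights, a replicate block, removal of probe sets that can bind several transcripts, each array left out in turn, no minimum difference, other margins, and tissues of the same extraction method or cultivar. Those that leave out endosperm and crease arrays, stem arrays, or some flag leaf arrays were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9.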

Results

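Transcript levels were measured in 9 tissues of triticale on 48 arrays. The vegetative tissues, with 35 arrays, were root (n = 3), coleoptile (n = 3), stem and leaf. Stem, the internodes between the crown and the second node, was sampled at Zadoks 21, 45, 59 and 75 (n = 3 each). Leaf was sampled at seedling stage (Z13, n = 3), tillering (Z23, n = 3), flag leaf at booting (Z49, n = 5), flag leaf at early senescence 22 days post anthesis (Z75, n = 3) and flag leaf at late senescence 30 days post anthesis (Z85, n = 3). The 5 seed tissues, with 13 arrays, were dissected at soft dough (Z85): embryo with scutellum (n = 3), endosperm (n = 3), crease, the vascular strand of the ventral groove (n = 3), pericarp, the inner seed coat layer (n = 2), and epiderm, the outermost layer (n = 2).

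Arrays of 1 group correlated at r of 0.946 to 0.994 across probe sets, which are not independent replicates. The median SD of a probe set between replicates was lowest in stem Z45, at 0.13 log2 units, and highest in leaf Z23, at 0.26. Leaf Z75 and leaf Z85 were the closest pair of groups (r = 0.995), followed by stem Z45 and stem Z59 (r = 0.983). Stem Z75 lay nearer to leaf Z85 (r = 0.955) than to stem Z59 (r = 0.910), and fewer probe sets separated it from leaf Z85 (5648) than from stem Z59 (8529). Among seed tissues, the arrays labelled endosperm lay nearest to pericarp (r = 0.968) and epiderm (r = 0.953). Crease was the farthest group from coleoptile and from every stage of stem and leaf, and its nearest group was pericarp (r = 0.882).

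**Figure D1:**
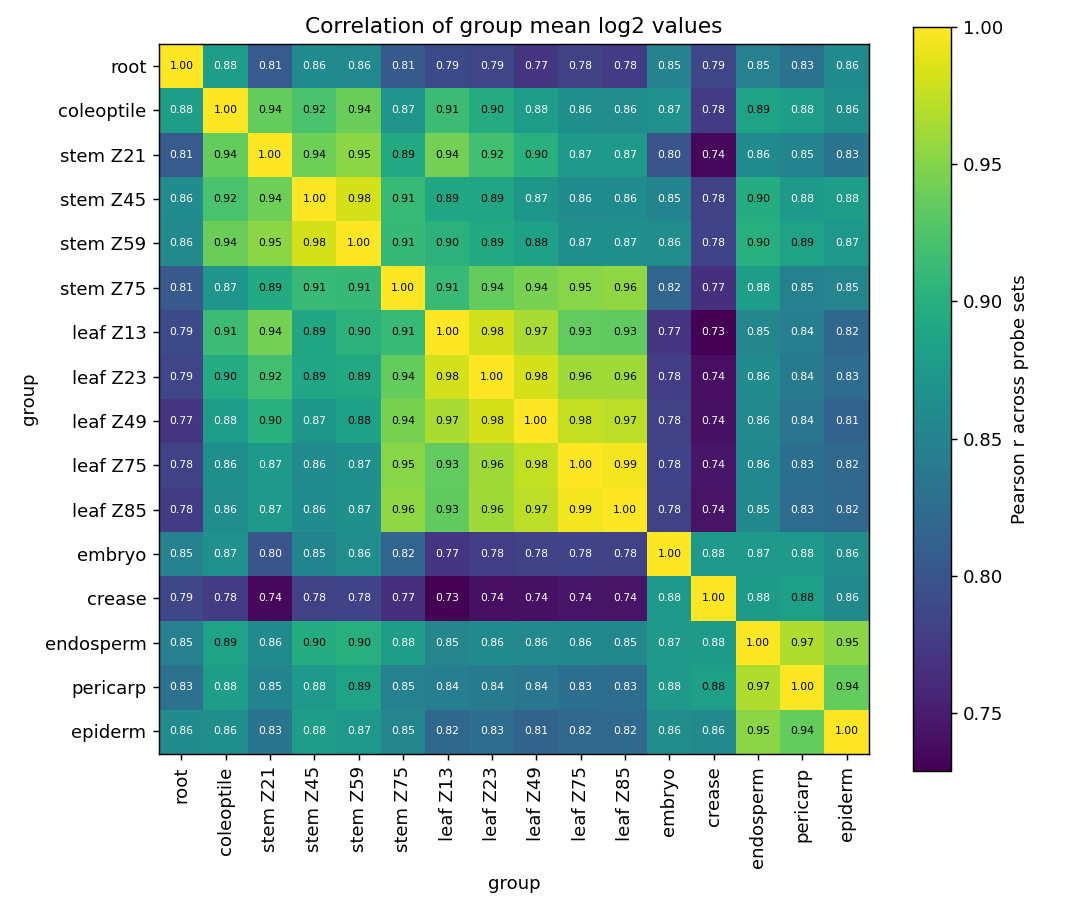
Pearson r across probe sets between the mean log2 values of the 16 groups, as colour and number. Leaf Z75 and leaf Z85 form the closest pair (0.995), and endosperm lies nearest to pericarp (0.968).

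Among the named genes, petC, CAT1, FBP and GAPN differed most between root and coleoptile. petC, which encodes the Rieske iron-sulfur protein of the thylakoid cytochrome complex, was 242-fold higher in coleoptile (13.19 ± 0.02 log2 units, SD, n = 3) than in root (5.27 ± 0.24, n = 3; adjusted p = 1.17e-29). The catalase gene CAT1 was at least 108-fold higher in coleoptile (11.30 against 4.55), the fructose-bisphosphatase gene FBP at least 59.3-fold (10.76 against 4.87), and GAPN, encoding the non-phosphorylating glyceraldehyde-3-phosphate dehydrogenase, at least 37.3-fold (9.73 against 4.51). XTH, a xyloglucan endotransglucosylase/hydrolase that cuts and rejoins cell wall xyloglucan, was 3.29-fold higher in coleoptile (11.67 ± 0.18 against 9.95 ± 0.13, adjusted p = 0.00605). Among unnamed probe sets, Ta.1896.1.S1_at was at least 688-fold higher in root (12.34 against 2.91), and LOC543448 (Ta.27793.2.S1_x_at) was at least 1629-fold higher in coleoptile (13.83 against 3.16). Of the tested probe sets, 8273 passed, 4241 higher in root and 4032 higher in coleoptile.

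Stem was compared between successive stages. From tillering to booting (Z21 to Z45), CAT1, FBP and GAPN fell. CAT1 went from 11.08 ± 0.17 to 8.08 ± 0.26 (SD, n = 3 each, 7.98-fold, adjusted p = 2.89e-14), FBP fell 3.56-fold to 10.26 and GAPN 2.08-fold to 10.31, while SAHH, the S-adenosylhomocysteine hydrolase of the methyl cycle, rose 2.02-fold to 14.58. petC differed by -0.75 log2 units, under the threshold. Of the 1792 leaf-over-root probe sets, 1243 fell and 38 rose (median difference -1.73, adjusted p = 1.34e-05 with an estimated correlation). In the root-over-leaf set, 462 of 1493 rose and 103 fell (median 0.23, adjusted p = 0.0411 with an estimated correlation). In all, 4164 probe sets rose and 3539 fell. The changes of SAHH and GAPN lie at the threshold and did not pass when 1 array was left out (SAHH 1.0 log2 units without stem Z45 replicate 1 and 0.998 without stem Z21 replicate 3, GAPN -0.995 without stem Z45 replicate 2).

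From booting to heading (Z45 to Z59), stem changed less, with 965 probe sets up and 892 down. CAT1 rose 2.69-fold, to 9.51 ± 0.22 (adjusted p = 1.29e-05). LOC780636 fell on both of its probe sets, at least 139-fold on Ta.7339.1.S1_at (10.76 to 3.64) and at least 91.4-fold on Ta.7339.1.S1_x_at (10.31 to 3.80). Of the leaf-over-root probe sets, 291 rose and 42 fell (median 0.48, adjusted p = 0.00362 with an estimated correlation). The count of 1857 was 1229 without stem Z45 replicate 1 (stem Z59 vs stem Z45).

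From heading to early senescence (Z59 to Z75), XTH fell 12.7-fold, from 9.67 ± 0.39 to 6.0 ± 0.17 (adjusted p = 8.39e-08). SAHH fell 6.18-fold (14.40 ± 0.09 to 11.77 ± 0.75) and the alpha-tubulin gene TUBA, a subunit of microtubules, fell 3.40-fold (13.89 ± 0.08 to 12.13 ± 0.15). CAT1 rose 8.73-fold, to 12.64 ± 0.31 (adjusted p = 5.65e-15), above its level at any earlier stem stage. Of the root-over-leaf probe sets, 603 fell and 101 rose (median -0.57, adjusted p = 4.82e-05 with an estimated correlation). In the leaf-over-root set 519 rose and 275 fell (median 0.25), with an adjusted p = 0.00173 at the preset correlation and an adjusted p = 0.423 with an estimated correlation. In all, 4292 probe sets rose and 4237 fell. Among unnamed probe sets, Ta.28750.2.A1_x_at rose 229-fold to 13.22 and Ta.9172.1.S1_at fell at least 942-fold to 2.90.

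Across the 4 stem stages, 15761 probe sets changed. XTH ranged over 4.74 log2 units (adjusted p = 2e-10) and TUBA over 1.84. The stem arrays also stood apart in a control probe set that no comparison used, that for 18S ribosomal RNA, which read 13.22 ± 0.06 on the 12 stem arrays and 7.81 ± 1.51 on the other 36. Other controls also differed between stem stages. The 3' minus 5' difference of the added dap transcript was 1.48 to 1.72 at Z21 and 1.77 to 1.84 at Z45, and 1.52 to 1.72 at Z59 and 1.79 to 1.86 at Z75. The added poly-A transcripts read 7.53 to 7.75 at Z59 and 7.99 to 8.59 at the other stem stages.

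**Figure D2:**
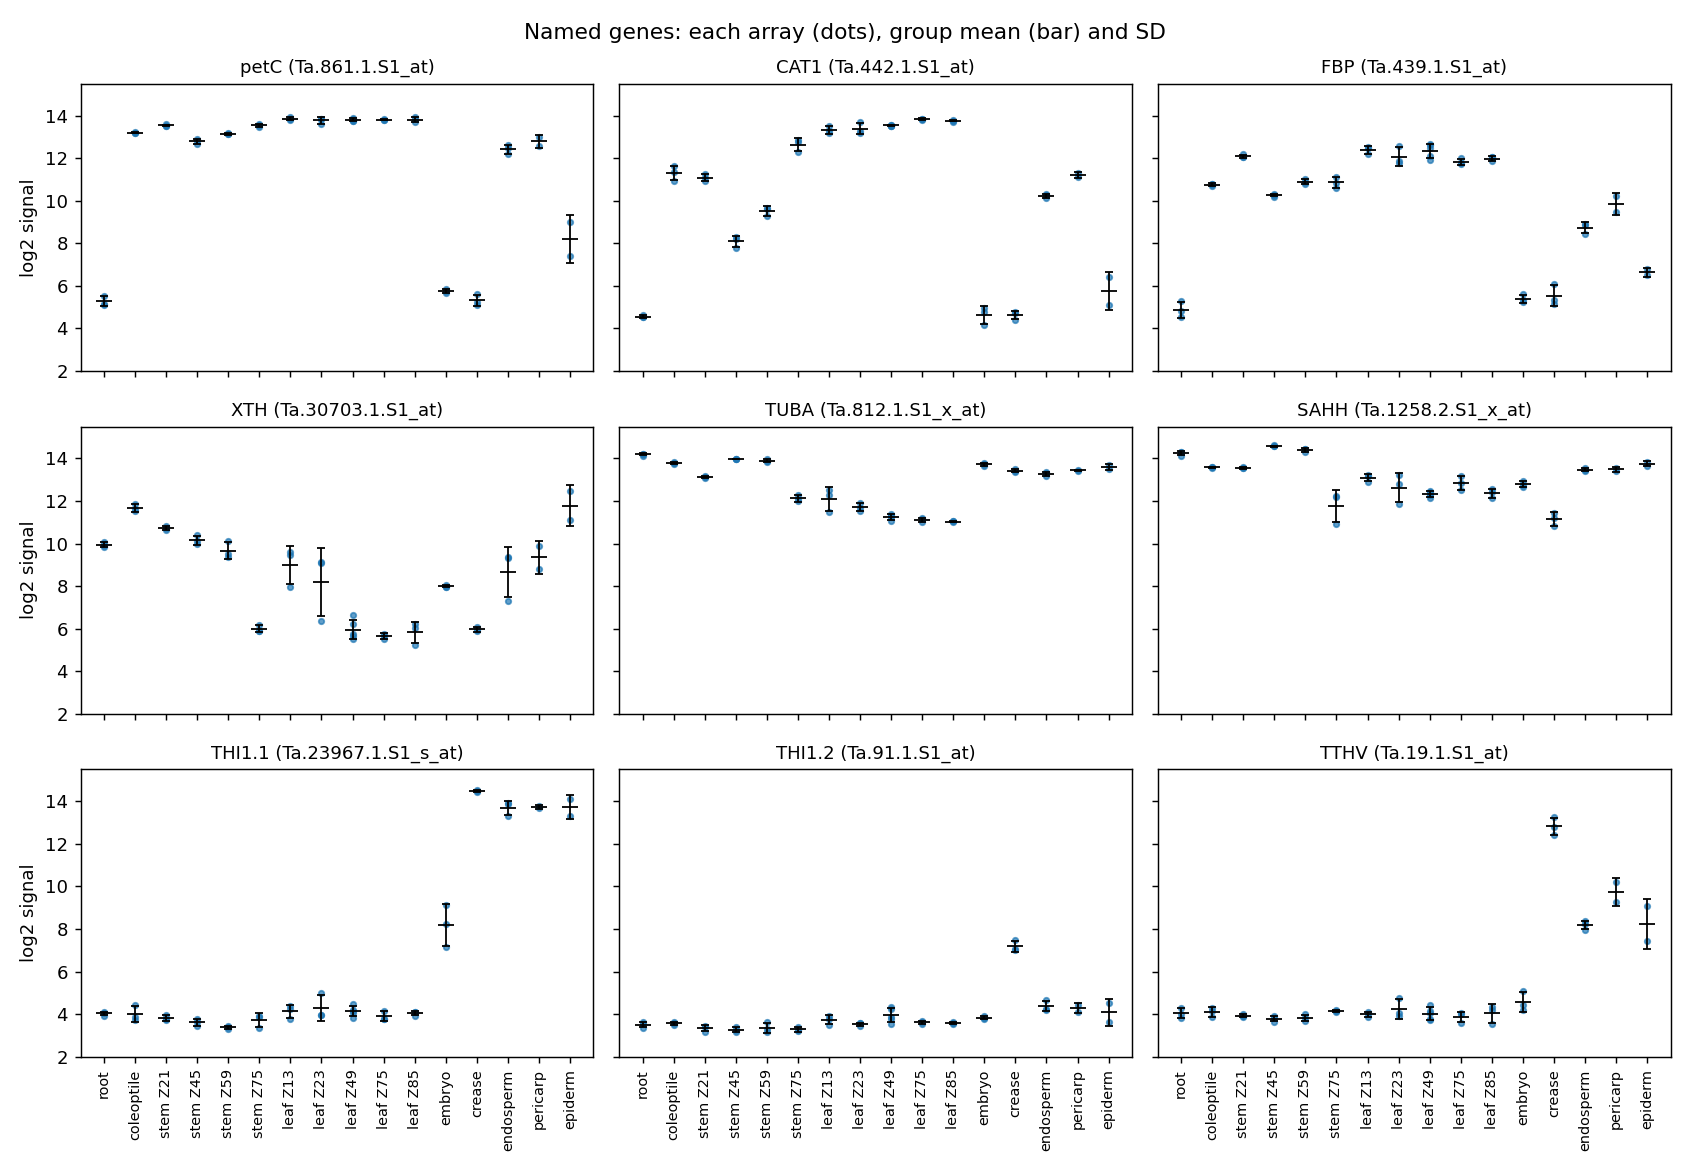
Log2 signal of 9 named genes in the 16 groups, with a dot for each array and a bar with whiskers for the group mean and SD. petC, CAT1 and FBP lie near 5 in root, embryo and crease and far higher in leaf, and the 3 thionin genes lie under 5 in every vegetative group.

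Leaf was compared between successive stages in the same way. From seedling to tillering (Z13 to Z23), no gene with a symbol passed. LOC780634 rose on both of its probe sets, at least 126-fold on TaAffx.120063.2.S1_s_at (3.14 to 10.11) and at least 90.1-fold on TaAffx.120063.1.S1_at (3.10 to 9.59). The unnamed Ta.17127.1.A1_at fell at least 164-fold (10.80 to 3.45) and TaAffx.85073.1.S1_at fell at least 105-fold (10.51 to 3.79). In all, 564 probe sets rose and 639 fell. The total of 1203 is sensitive to single arrays and to the shared spread: it was 13 with only the compared arrays in the fit, 786 without leaf Z23 replicate 2, 2619 without leaf Z23 replicate 1 and 1890 without leaf Z13 replicate 1 (leaf Z23 vs leaf Z13).

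Between tillering leaf and flag leaf at booting (Z23 to Z49), XTH fell 4.68-fold, from 8.18 ± 1.60 (n = 3) to 5.96 ± 0.46 (n = 5, adjusted p = 0.000781). The difference was -3.15 log2 units without leaf Z23 replicate 2 and -1.75 without leaf Z23 replicate 3, and did not pass with only the compared arrays in the fit (XTH: leaf Z49 vs leaf Z23). TaAffx.70216.1.S1_s_at rose 32.8-fold to 10.27 and Ta.13337.2.S1_x_at fell 76.1-fold to 5.75. The leaf-over-root set had a median difference of 0.16 and a mean of 0.03, with 47 members up and 105 down and an adjusted p = 0.454 with an estimated correlation. In all, 542 probe sets rose and 848 fell, a total of 1390 that was 168 with only the compared arrays in the fit, 888 without leaf Z23 replicate 3 and 2395 without leaf Z23 replicate 2 (leaf Z49 vs leaf Z23).

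From booting to early senescence of the flag leaf (Z49 to Z75), 1723 probe sets rose and 832 fell. The largest changes were those of the unnamed Ta.28289.1.S1_a_at, which rose at least 399-fold (3.54 to 12.18), and Ta.21419.1.S1_at, which fell 161-fold (12.37 to 5.04). No gene with a symbol passed. The level of petC was 13.81 ± 0.06 at booting and 13.80 ± 0.03 at early senescence, and that of CAT1 13.54 ± 0.03 and 13.83 ± 0.04. In the leaf-over-root set, 257 probe sets fell and 50 rose (median -0.22, adjusted p = 9.07e-07 at the preset correlation and adjusted p = 0.199 with an estimated correlation).

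From early to late senescence (Z75 to Z85), 12 probe sets passed in limma's test, 5 up and 7 down, and 3281 had an unadjusted p under 0.05. With quantile normalization applied again, 4 rose and 2 fell. Ta.23970.1.A1_x_at rose 4.96-fold (8.05 to 10.36, adjusted p = 0.0387) and Ta.13991.1.S1_x_at fell 8.17-fold (9.66 to 6.63, adjusted p = 0.0387). The leaf-over-root set differed by a median of 0.02 and a mean of -0.01 (adjusted p = 0.995 with an estimated correlation). Leaving out 1 array gave 4 probe sets without leaf Z75 replicate 1, 35 without leaf Z75 replicate 2, 2 without leaf Z75 replicate 3, 22 without leaf Z85 replicate 1 and 0 without leaf Z85 replicate 2 (leaf Z85 vs leaf Z75).

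Across the 5 leaf stages, 10805 probe sets changed. XTH ranged over 3.35 log2 units, from 9.0 ± 0.90 at seedling stage to 5.65 ± 0.13 at early senescence. TUBA ranged over 1.07 log2 units, from 12.10 ± 0.56 to 11.03 ± 0.04. Its range was under the threshold without leaf Z13 replicate 3 (0.85) or replicate 2 (0.97) and with median scaling (0.98) (TUBA: leaf across stages).

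**Figure D3:**
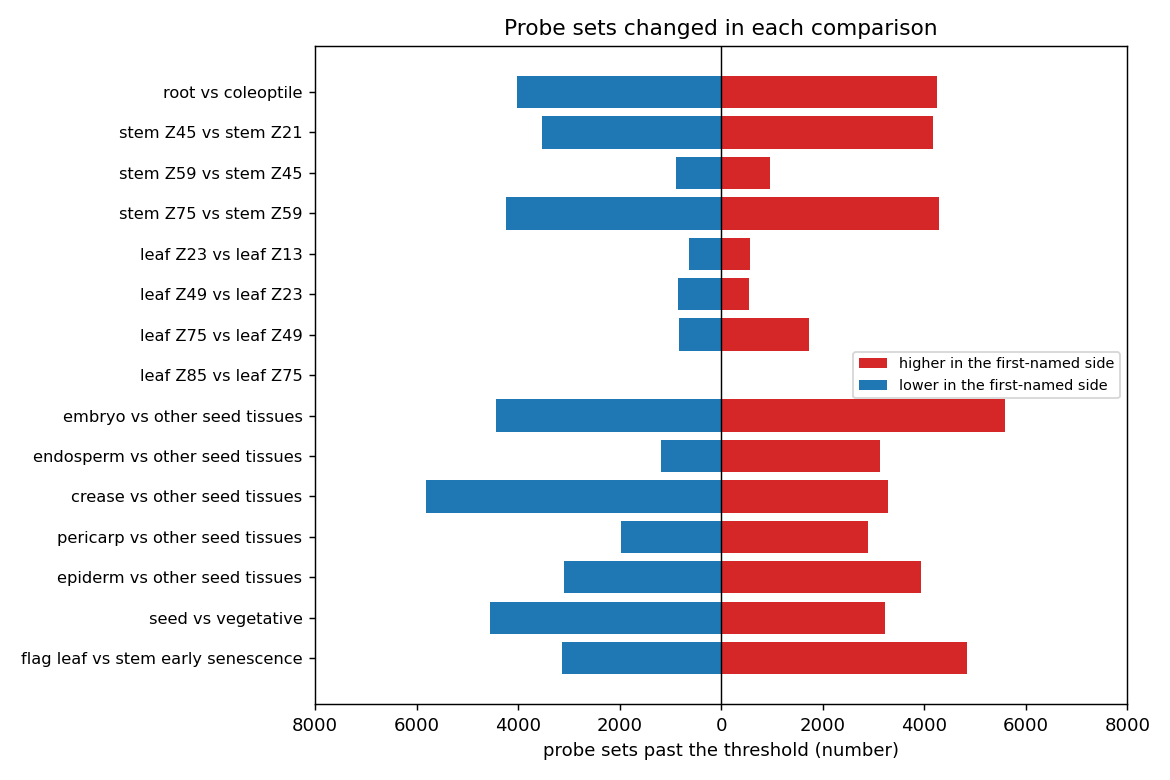
Number of probe sets past the threshold in each comparison, higher in the first-named side to the right and lower to the left. Bars run from 12 probe sets in leaf Z85 against leaf Z75 to 10018 in embryo against the other seed tissues.

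The change from booting to Zadoks 75 was tested for a difference between flag leaf and stem, a comparison named flag leaf vs stem early senescence below. Booting is Z49 in the flag leaf and Z45 in stem, so the starting stages are not the same. XTH fell in stem from 10.16 ± 0.22 at Z45 to 6.0 ± 0.17, while it read 5.96 ± 0.46 and 5.65 ± 0.13 in the flag leaf, and the difference between the changes was 3.85 ± 0.65 log2 units (SE, adjusted p = 1.59e-05). At booting the flag leaf already read close to the level that stem reached, so unlike starting levels enter this difference. TUBA read 13.96 and 12.13 in stem and 11.25 and 11.12 in the flag leaf, a difference between the changes of 1.71 ± 0.20 log2 units (SE, adjusted p = 8.99e-09). Only members of the fixed lists were named by the rule in this contrast, where overlap of 2 groups is not defined. Outside the lists, SAHH differed by 3.33 log2 units. CAT1 went the other way and rose more in stem, with 8.08 and 12.64 there and 13.54 and 13.83 in the flag leaf. In all, 7978 probe sets changed differently, 4836 with the higher change in the flag leaf and 3142 with the higher change in stem. In the leaf-over-root set 884 members moved lower in the flag leaf relative to stem and 73 higher (median -1.08, adjusted p = 0.00369 with an estimated correlation). In the root-over-leaf set 595 moved higher and 41 lower (median 0.73, adjusted p = 4.82e-05 with an estimated correlation). The median of all tested probe sets in this contrast was -0.11 log2 units.

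**Figure D4:**
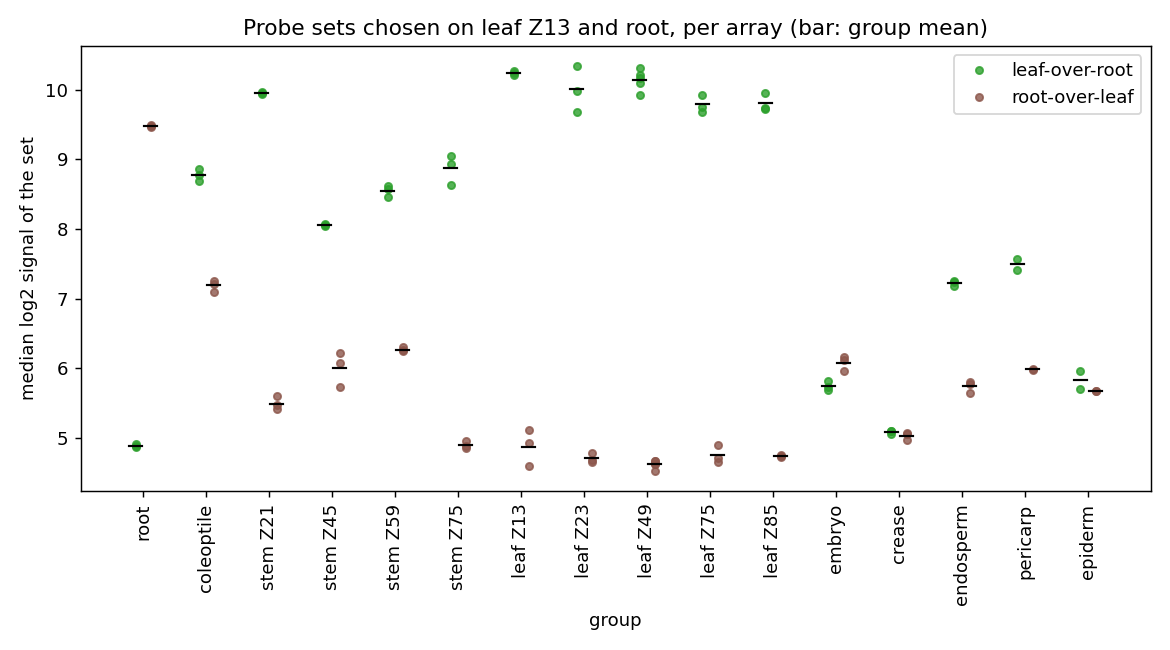
Median log2 signal per array of the leaf-over-root and the root-over-leaf probe sets, with a bar for the mean of each group. The sets were chosen on leaf Z13 and root, and the leaf-over-root set lies near 7 in endosperm and pericarp and near 5 in crease.

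Each seed tissue was compared with the mean of the other 4. The p-values rest on the spread between replicates and not on that between tissues. Among the probe sets that passed, the arrays of the tissue overlapped no other seed array in 6752 for embryo, 1071 for endosperm, 5676 for crease, 1968 for pericarp and 3867 for epiderm. Embryo was marked by LOC543497 (Ta.2798.1.S1_s_at), at least 2009-fold higher than in the other seed tissues (14.09 against 3.12), and LOC543480 (Ta.25025.1.S1_at), at least 743-fold higher (13.83 against 4.29). Genes of thionins, small antimicrobial peptides, were lower in embryo: THI1.1 read 8.17 ± 0.98 (n = 3) against a mean of 13.90 (53.1-fold, adjusted p = 1.5e-22), TTHV 4.56 ± 0.46 against 9.75 (at least 36.6-fold), and THI1.2 3.83 ± 0.07 against 4.98. The mean of 4.98 for THI1.2 rests on crease (7.18). Endosperm (4.37), pericarp (4.28) and epiderm (4.075) lay under 4.87, where signal can be background, so no fold is given. In all, 5581 probe sets were higher in embryo and 4437 lower. Among leaf-over-root probe sets 565 were lower and 138 higher (median -0.43), with an adjusted p = 0.103 with an estimated correlation. The difference of THI1.2 did not pass against embryo's own extraction method alone (-0.49) or when endosperm and crease arrays were left out (-0.34) (THI1.2: embryo vs other seed tissues).

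The arrays labelled endosperm held probe sets that stood out from every other seed tissue, led by the unnamed Ta.4275.1.S1_at, which was at least 175-fold higher than the mean of the others (12.08 against 4.63). THI1.1 was 2.24-fold higher (13.69 ± 0.35 against 12.53, adjusted p = 0.000164) on Ta.23967.1.S1_s_at, against a mean that includes 8.17 in embryo, while its other probe set differed by 0.78 log2 units, under the threshold. On these arrays petC read 12.42 ± 0.22 and CAT1 10.23 ± 0.09, against 12.79 ± 0.30 and 11.21 ± 0.13 in pericarp and 5.31 ± 0.26 and 4.63 ± 0.20 in crease. Of the leaf-over-root probe sets, 798 were higher and 17 lower in endosperm (median 0.86, adjusted p = 4.82e-05 with an estimated correlation). In all, 3130 probe sets were higher and 1184 lower. Between endosperm and pericarp alone 3742 probe sets differed, fewer than between endosperm and epiderm (5022) or crease (10255).

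The arrays labelled crease had the highest thionin levels of the series. TTHV read 12.83 ± 0.41 (n = 3) against a mean of 7.68 in the other seed tissues (35.4-fold, adjusted p = 3.26e-21), THI1.2 7.18 ± 0.25 against 4.14 (at least 8.22-fold), and THI1.1, on Ta.23967.1.S1_x_at, 14.06 against 11.21 (7.25-fold). petC was 22.3-fold lower (5.31 ± 0.26 against 9.79), XTH 11.2-fold lower (5.96 ± 0.10 against 9.45) and SAHH 4.76-fold lower (11.34 ± 0.28 against 13.59). In the leaf-over-root set, 932 probe sets were lower and 40 higher (median -1.07, adjusted p = 0.000995 with an estimated correlation), and in the root-over-leaf set 440 were lower and 76 higher (median -0.30, adjusted p = 0.0101 with an estimated correlation). In all, 3290 probe sets were higher and 5824 lower. With quantile normalization applied again, 4117 were higher and 5397 lower.

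In pericarp CAT1 was 30.0-fold higher than the mean of the other seed tissues (11.21 ± 0.13, n = 2, against 6.31, adjusted p = 1.36e-21), FBP 9.71-fold (9.85 ± 0.52 against 6.57) and GAPN 6.26-fold (9.03 ± 0.54 against 6.38). Endosperm minus pericarp was -1.13 log2 units for FBP, -1.38 for GAPN and, under the threshold, -0.99 for CAT1. THI1.1 was 2.32-fold higher (13.73 ± 0.08 against 12.52) on Ta.23967.1.S1_s_at. That mean is low through embryo, since endosperm read 13.69 and epiderm 13.73, and the other probe set of THI1.1 differed by 0.67 log2 units (adjusted p = 0.163). Of the leaf-over-root probe sets, 918 were higher and 27 lower (median 1.08, adjusted p = 1.34e-05 with an estimated correlation). In all, 2885 probe sets were higher and 1981 lower.

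In epiderm XTH read 11.78 ± 0.97 (n = 2, 11.09 and 12.46) against a mean of 7.99 in the other seed tissues (13.8-fold, adjusted p = 1.73e-08). The difference was 3.10 log2 units without epiderm replicate 2 and 4.47 without epiderm replicate 1 (XTH: epiderm vs other seed tissues). SAHH was 2.03-fold higher (13.74 ± 0.12 against 12.72) and THI1.1 2.32-fold higher (13.73 ± 0.57 against 12.52) on Ta.23967.1.S1_s_at, with 0.90 log2 units on its other probe set, under the threshold. The unnamed Ta.556.1.S1_at was at least 267-fold higher (12.65 against 4.59). Among leaf-over-root probe sets 504 were lower and 148 higher (median -0.48), with an adjusted p = 0.125 with an estimated correlation. In all, 3940 probe sets were higher and 3094 lower. Against crease alone, which shares the extraction method, THI1.1 differed by -0.74 log2 units and the leaf-over-root set by a median of 0.32, the opposite directions (THI1.1: epiderm vs other seed tissues, leaf-over-root set median: epiderm vs other seed tissues). SAHH did not pass without epiderm replicate 2 (0.94), crease replicate 3 (0.98) or pericarp replicate 1 (0.998), and THI1.1 did not pass without epiderm replicate 1 (0.81) (SAHH: epiderm vs other seed tissues).

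Seed and vegetative tissues were set apart by THI1.1, which was at least 451-fold higher in seed (12.76 against 3.94, adjusted p = 7.57e-38). Its group means ran from 8.17 in embryo to 14.47 in crease, and from 3.39 to 4.30 in the vegetative groups. THI1.2 was 1.23 log2 units higher in seed (4.75 against 3.52), and did not pass when endosperm and crease arrays were left out (0.55 log2 units) (THI1.2: seed vs vegetative). Ta.23142.1.S1_x_at was at least 709-fold higher in seed (12.81 against 3.34) and Ta.27457.5.S1_x_at 407-fold higher in vegetative tissue (13.76 against 5.10). In all, 3222 probe sets were higher in seed and 4553 in vegetative tissue. Of these 7775, 435 had no overlap between seed and vegetative arrays. The p-values rest on the spread between replicates and not on that between tissues, so a passing difference of means can come from some of the tissues only.

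In all, 2007 probe sets were enriched in 1 tissue. Root had 657, crease 429, leaf 345, embryo 227, coleoptile 173, epiderm 91, endosperm 42, stem 26 and pericarp 17, which was 35 without pericarp replicate 1 (tissue-enriched probe sets in pericarp). The genes with a symbol among them were CAT1 in leaf (2.26 log2 units above the next tissue) and the thionin genes TTHV (3.09) and THI1.2 (2.81) in the arrays labelled crease. The counts and genes of crease and endosperm follow the labels, and an exchange of these labels was not excluded. When every stage counted as its own tissue, leaf had 93, epiderm 60, coleoptile 56 and stem 17, and CAT1 lay 0.93 log2 units above the next group (CAT1 margin in leaf, tissue-enriched probe sets in leaf, tissue-enriched probe sets in epiderm, tissue-enriched probe sets in coleoptile, tissue-enriched probe sets in stem). The probe sets with the largest margin of each tissue were that of LOC543497 in embryo, 10.20 log2 units on Ta.2798.1.S1_s_at, Ta.1896.1.S1_at in root (9.43), Ta.9717.1.A1_a_at in coleoptile (8.43), Ta.1120.1.S1_at in leaf (7.17) and Ta.4275.1.S1_at in endosperm (7.11). In crease LOC780587 led (Ta.11127.2.S1_a_at, 5.95), in stem Ta.14005.2.S1_s_at (4.95), in epiderm Ta.8284.1.S1_at (4.36) and in pericarp TaAffx.106825.1.S1_at (4.16). Root and coleoptile differ from the other tissues in cultivar, age and extraction method as well.

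**Figure D5:**
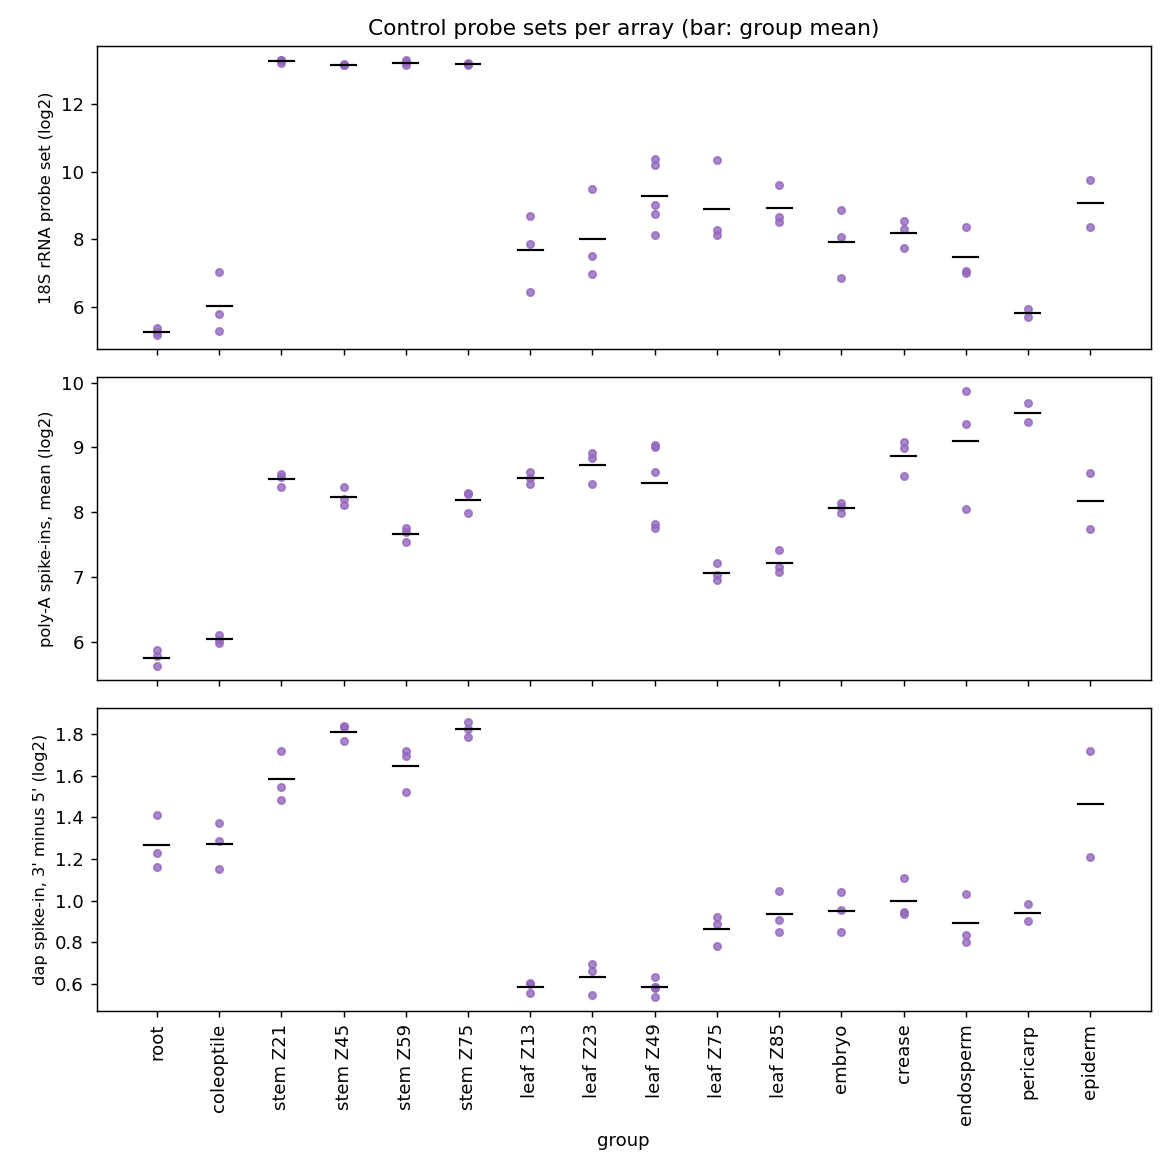
Control probe sets on each array (dots) with group means (bars): 18S ribosomal RNA, the mean of the added poly-A transcripts, and the 3' minus 5' difference of the added dap transcript, in log2 units. The 12 stem arrays read 13.15 to 13.32 for 18S ribosomal RNA, above all 36 other arrays.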

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

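The tests of the stem control probe sets and of regrouped stages were chosen after the results were seen, and the test of the interaction was chosen before.

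The change from booting to Zadoks 75 differed between flag leaf and stem, by the test of the difference itself, in 7978 probe sets. Among members of the fixed lists, XTH differed by 3.85 log2 units and TUBA by 1.71. Outside the lists, SAHH differed by 3.33, and CAT1 went the other way and rose more in stem. The leaf-over-root set differed by a median of -1.08 log2 units and the root-over-leaf set by 0.73. Of 100 splits of the same arrays, the real one included, 7 gave at least as many probe sets (highest other 15004), but these move arrays between leaf and stem, so the structure of the samples enters their counts, and they do not exclude chance. With stages regrouped inside each tissue, 2 of 100 splits gave as many (highest other 8689), and the 86 that mixed stem stages gave at most 1878, so the count rests largely on the change in stem.

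The 18S ribosomal RNA control probe set, which no comparison used, read 13.22 ± 0.06 on the 12 stem arrays, against 7.81 ± 1.51 on the other 36. Shortened stem RNA alone is argued against, since the dap transcript, which is added to the RNA and is no plant RNA, showed a larger 3' minus 5' difference on stem arrays (1.72 ± 0.13 against 0.91 ± 0.28), 2.83 SD of the other arrays above their mean. The epiderm arrays, at 1.21 to 1.72, reached into the stem range of 1.48 to 1.86. Plant transcripts had larger differences on stem arrays too, sucrose synthase 6.81 ± 0.53 against 4.66 ± 0.46 and glucose-6-phosphate dehydrogenase 2.51 ± 0.27 against 1.54 ± 0.30. Shortened RNA as a part of the cause stays open. A labelling or hybridisation batch of the stem arrays may contribute, and the same 2.83 SD lie on the side it predicts. This is no separate support, since dap is itself one of the controls in which the stem arrays stand apart. A batch also cannot be separated from tissue where all stem arrays share it. The further column that stem RNA passed through, and a difference in the RNA of stem tissue itself, were not tested. Whether the differences of dap and the poly-A transcripts between stem stages go with the stage changes was not tested either.

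In leaf Z49, the group of 5 arrays, Dixon's ratio set 0 of 31 measures apart. That ratio looks for 1 array apart from the rest and can miss a pair. Replicates 4 and 5 differ together from replicates 1 to 3 in the added poly-A transcripts (7.78 against 8.89).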

How the results depend on the processing

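The alternatives that leave out endosperm and crease arrays, stem arrays, or some flag leaf arrays were chosen after seeing the data, the others before. Of 977 values of counts, 895 lay within 1.5 times the reported count. Of 1062 values of named genes, 1042 kept direction and side of the threshold, 19 kept direction only and 1 turned; of 410 set medians, 5 no longer passed, 5 newly passed and 3 of those that had passed at the preset correlation turned. Other tests of the gene lists were not run because no list had 5 genes, and with all 48 arrays compared, a fit of the compared arrays is the same fit for seed against vegetative and the enriched probe sets. Signal near background limits genes such as COR410 and PFK, which were dim in every group. The replicate numbers do not pair the samples over the groups of any comparison: correlations of same-number deviations ran from -0.219 to 0.272. Embryo and crease alone had all 3 above 0.1 (0.101, 0.106 and 0.186). With the replicate number as a block, root vs coleoptile gave 8278 probe sets, leaf Z49 vs leaf Z23 1505, leaf Z75 vs leaf Z49 2442 and leaf Z85 vs leaf Z75 16, embryo vs other seed tissues 10031 and crease vs other seed tissues 9152, and no count moved by over 1.5 times. Where no cause is named, the cause was not tested.

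The direction turned for 3 results that had passed. The pericarp median of the root-over-leaf set was -0.0017 within the same extraction method and -0.045 without endosperm and crease, against 0.07 reported (root-over-leaf set median: pericarp vs other seed tissues). That median had passed at the preset correlation only (adjusted p = 0.302 with an estimated correlation). Within the same extraction method THI1.1 was -0.74 (THI1.1: epiderm vs other seed tissues) and the epiderm median of the leaf-over-root set 0.32 (leaf-over-root set median: epiderm vs other seed tissues), which had also passed at the preset correlation only (adjusted p = 0.125 with an estimated correlation). Medians near 0 that had not passed changed sign as well. In leaf Z85 vs leaf Z75 the leaf-over-root median went from 0.02 to -0.035 without leaf Z85 replicate 2 and the root-over-leaf median from -0.0067 to 0.0083 without leaf Z75 replicate 1. In epiderm the root-over-leaf median went from -0.08 to 0.03 within the same extraction method (leaf-over-root set median: leaf Z85 vs leaf Z75, root-over-leaf set median: leaf Z85 vs leaf Z75, root-over-leaf set median: epiderm vs other seed tissues). With only the compared arrays in the fit, leaf Z23 vs leaf Z13 gave 13, leaf Z49 vs leaf Z23 168 and leaf Z85 vs leaf Z75 5; quantile normalization again gave 6 for the last. Array weights gave 1846, 2329 and 49 for these 3. Epiderm against crease alone gave 11122. Quantile normalization again also shifted the split of calls. For stem Z75 vs stem Z59 it gave 4082 higher and 4201 lower, against 4292 and 4237 reported. For leaf Z75 vs leaf Z49 it gave 1474 higher and 980 lower, and for the difference between flag leaf and stem 4438 and 3624.

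2 settings change the counts by construction. The first leaves out probe sets that can bind several transcripts, with 48453 left to test, and the second drops the minimum difference. In that order the counts were 5319 and 15663 for root vs coleoptile, 5008 and 16097 for stem Z45 vs stem Z21, 1177 and 4767 for stem Z59 vs stem Z45, 5481 and 16595 for stem Z75 vs stem Z59, 10399 and 25577 for stem across stages, 730 and 3575 for leaf Z23 vs leaf Z13, 868 and 4143 for leaf Z49 vs leaf Z23, 1690 and 11625 for leaf Z75 vs leaf Z49, 7139 and 26407 for leaf across stages, 6430 and 22896 for embryo vs other seed tissues, 2603 and 13897 for endosperm vs other seed tissues, 5759 and 26906 for crease vs other seed tissues, 3107 and 11516 for pericarp vs other seed tissues, 4365 and 15612 for epiderm vs other seed tissues, 4930 and 31051 for seed vs vegetative, 5162 and 12865 for flag leaf vs stem early senescence. For leaf Z85 vs leaf Z75 the first gave 0, where 3281 had an unadjusted p under 0.05 in limma's test of all probe sets, near the share that no change at all would give.

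Among tissue-enriched probe sets, a margin of 1 gave 6557 and a margin of 3 gave 820 in all. In that order, tissue-enriched probe sets in root were 1458 and 345, tissue-enriched probe sets in coleoptile were 442 and 82, tissue-enriched probe sets in stem were 231 and 7, tissue-enriched probe sets in leaf were 1318 and 105, tissue-enriched probe sets in embryo were 1188 and 101, tissue-enriched probe sets in endosperm were 154 and 14, tissue-enriched probe sets in crease were 1198 and 147, tissue-enriched probe sets in pericarp were 124 and 3, tissue-enriched probe sets in epiderm were 444 and 16. With every stage as its own tissue, coleoptile had 56, stem 17, leaf 93 and epiderm 60. Without probe sets that can bind several transcripts, root had 436 and crease 280. Without endosperm and crease arrays pericarp had 238 and epiderm 141, and without stem arrays leaf had 590, where fewer tissues are compared.

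Leaving out 1 array gave 1229 to 2084 for stem Z59 vs stem Z45 (1229 without stem Z45 replicate 1), 786 to 2619 for leaf Z23 vs leaf Z13 (1890 without leaf Z13 replicate 1, 2619 without leaf Z23 replicate 1, 786 without leaf Z23 replicate 2), 888 to 2395 for leaf Z49 vs leaf Z23 (2395 without leaf Z23 replicate 2, 888 without leaf Z23 replicate 3), 0 to 35 for leaf Z85 vs leaf Z75 (35 without leaf Z75 replicate 2, 22 without leaf Z85 replicate 1, 4 without leaf Z75 replicate 1, 2 without leaf Z75 replicate 3, 0 without leaf Z85 replicate 2) and 15 to 35 for tissue-enriched probe sets in pericarp (35 without pericarp replicate 1). A group left with 1 array is assumed to vary like the others.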

Other observations

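The tests of the wheat control transcripts, of the overlap between leaf and stem, and of exchanged labels were chosen after the results were seen.

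Wheat transcripts that the array carries as controls were outside the comparisons, and their p-values were adjusted among 25 such probe sets. Sucrose synthase, which splits sucrose for growing and storing tissue, rose in stem on its 3' probe set from 10.13 ± 0.33 at Z21 to 12.87 ± 0.16 at Z45 (6.68-fold, limma adjusted p = 2.36e-13) and fell to 11.87 at Z59 and 10.58 at Z75. Its 3' minus 5' difference grew from 6.32 ± 0.40 at Z21 to 7.30 ± 0.32 at Z45, so the rise was smaller on the 5' probe set. That of the added dap transcript grew as well, from 1.58 ± 0.12 to 1.81 ± 0.04, and its part in the 6.68-fold was not tested. In seed sucrose synthase was highest in crease, at 12.44 ± 0.13 (1.95-fold over the other seed tissues, adjusted p = 9.24e-06), with 3.14-fold on the middle and 3.68-fold on the 5' probe set. Glucose-6-phosphate dehydrogenase, of the oxidative pentose phosphate pathway, was 3.21-fold lower in crease (7.37 ± 0.24) than in the other seed tissues on the 3' probe set (adjusted p = 9.86e-12), 3.10-fold on the middle and 2.60-fold on the 5' one. The probe sets of a cytochrome P450 of the CYP86 family differed in size of change. In pericarp it was 7.88-fold higher than in the other seed tissues on the 3' probe set (9.61 ± 0.83), 2.25-fold on the middle and 2.11-fold on the 5' one. In crease it was at least 14.3-fold lower on the 3' probe set (4.16 ± 0.80) and under the 2-fold threshold on the middle (1.54-fold) and the 5' one (1.61-fold).

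The calls of flag leaf and stem between booting and Zadoks 75 share no arrays. Of 1723 probe sets that rose in the flag leaf and 3757 that rose in stem, 615 rose in both, against 106 for independent lists, and of 832 and 4295 that fell, 320 fell in both, against 58.4. Opposite directions gave 137, against 121, and 97, against 51.1. In ratios, these are 5.81 and 5.48 for the same direction and 1.13 and 1.90 for opposite directions. XTH and TUBA fell in stem and did not pass in the flag leaf.

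The arrays labelled endosperm held leaf-over-root transcripts close to pericarp levels, while those labelled crease held the highest thionins (TTHV 12.83 against 8.18 in endosperm). From the leaf-over-root set, 308 probe sets were chosen that were also at least 3 log2 units higher in pericarp than in embryo and in crease. Their median was 9.61 in endosperm and 10.23 in pericarp, and, low by that choice, 4.67 in crease and 4.79 in embryo. Carry-over of a green pericarp layer is a possible account and met the limit set for it. The median distance of these probe sets to pericarp was -0.55 log2 units (68.1% of the pericarp level). The 10th percentile lay 0.866 log2 units below the median, inside the limit of 1 set before, when endosperm's closeness to pericarp was already known. That limit cannot tell carry-over from expression of the same genes in the sampled tissue, so no share is assigned to carry-over. Of the 308, 25 lay more than 1 below that median and the lowest distance was -6.07, so a common share does not hold for all of them. Probe sets that are low in endosperm cannot judge where the signal of the others came from. An exchange of labels between endosperm and crease stays open, since 0 spike-in measures sorted all of these arrays by extraction method: the dap difference set epiderm (1.21 to 1.72) apart from embryo and pericarp, but crease (0.94 to 1.11) and endosperm (0.80 to 1.03) both lay on the side of the latter, and expression in the endosperm itself was not tested.

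For the flag leaf, replicates 4 and 5 at booting differ from replicates 1 to 3 in the added poly-A transcripts (7.78 against 8.89), nearer to leaf Z75 and Z85 (7.14). A labelling batch that replicates 4 and 5 share with leaf Z75 could then have shaped the change from Z49 to Z75. The median share of the change left against replicates 4 and 5 was 0.985, which argues against a batch shared in that way. The dap difference does not place these replicates with the later stages. It was 0.61, against 0.57 in replicates 1 to 3 and 0.90 in leaf Z75 and Z85. A batch that sets all Z49 arrays apart from Z75 would leave the change whole as well, so the share cannot judge it. The count was 2436 against replicates 1 to 3 and 3004 against replicates 4 and 5, with 1770 shared. Of the 2436, 99.4% had the same direction against replicates 4 and 5, and 70 probe sets differed between both parts of the group.

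Other splits of the same arrays were counted, including the real one. The real split alone reached its count, 1 in 100 or in 56, for stem across stages (15761, highest other 11997), leaf across stages (10805, 7237), leaf Z75 against Z49 (2555, 1101), embryo (10018, 5112), crease (9114, 6457) and seed against vegetative (7775, 2). For each taken alone, that speaks against arrays that are all alike. The shares were not adjusted over the comparisons, and the other splits mix stages or tissues, so the structure of the samples enters their counts. By themselves they do not exclude chance. For leaf Z49 vs leaf Z23 1 split of 56 was as large (1390, highest other 1120), but the count was 888 without leaf Z23 replicate 3 and 168 with only the compared arrays in the fit, so this count is the least secure of those. For endosperm the splits do not exclude chance either, as 11 of 100 gave as many (4314, highest other 8561), and here too splits that mix tissues carry the structure of the samples into their counts. Leaving out 1 array gave 3891 to 4685 for endosperm. With 10 splits the share is too small to be judged for root and coleoptile (8273, highest other 13), stem Z45 and Z21 (7703, 15), stem Z59 and Z45 (1857, 40), stem Z75 and Z59 (8529, 99) and leaf Z85 and Z75 (12, 11). For leaf Z23 and Z13, 2 of 10 splits gave as many, and leaf Z13 replicate 1 with leaf Z23 replicates 2 and 3 against the others gave 1501, more than the real 1203.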
